A study of Mus musculus with 84 samples.

How the data were processed

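Bulk RNA sequencing of ventrolateral striatum from 84 naive adult mice was analysed, 44 labelled High Drinker and 40 labelled Low Drinker, from the SOT and NOT lines. Per the labels' protocols, brains were flash frozen, the tissue was dissected by hand, RNA was isolated with Trizol, amplified cDNA was made with an Ovation RNA-Seq kit, and libraries were prepared with an Illumina TruSeq DNA kit. They were sequenced 6 per lane as single-end reads of 100 bp. Amplified cDNA holds duplicate molecules that gene counts cannot tell apart, and the kits as described do not mark strand.

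The authors deposited raw read counts per gene, 1 column per animal, in the layout of featureCounts. Per the submitters' processing notes, FastQC, STAR, featureCounts from Subread and edgeR were used with genome build mm10. Their versions, and the strand and multi-mapping settings of counting, are not given in the sources used here. The table holds 43629 genes by Ensembl identifier, 0 entries that name no gene (a share of 0%) and 12117 genes with a count of 0 in every library. Symbols were found for 42462 identifiers in the GENCODE annotation of the same build, 42504 lay on the same chromosome there and 33546 had the same start and end, so coordinates are those of the deposited table. All 37 mitochondrial genes had a total count of 0, so the share of mitochondrial reads could not be used as a quality measure and the list of mitochondrially encoded genes had no tested member. Cells giving exon strands end early for genes with many exons, and the sign of the first exon was used.

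Groups and sex come from the labels. The sample numbers that end the titles run in 3 sets, taken as sheet sets (48, 30 and 6 libraries), and set was a term in the models because the lines were unequally spread over the sets. That these sets are technical batches is an inference from the numbering. Animals carry separate animal numbers, and 0 of 3486 library pairs were identical, with the lowest chi-square per gene of any pair at 7.75 (median 78.8). Depth differed by less than a factor of 2 between the shallowest library (22190363) and the deepest (41300401). At these depths the spread between animals, not counting error, sets the precision of genes above a few CPM.

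The line, sex and interaction tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM normalization, filterByExpr, model with set, sex and line). Benjamini-Hochberg adjustment covered the 17071 tested genes at a threshold of 0.05. CPM values are counts scaled to the library total after TMM normalization, given as mean ± SD over animals. Variability was tested with limma 3.58.1 on absolute deviations of log2 CPM (prior count 2) from the median of line and sex. Gene lists, fixed before the data were examined, were tested with camera on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 37 lists written, 35 had enough tested members, and the Y-linked list was used for the sex comparison. Correlations were computed on residual log2 CPM of 3000 genes, pairs were counted where Pearson r differed by over 0.5, and line labels were permuted 100 times within sex and set. Modules came from average-linkage clustering cut into 40 clusters, keeping those of 30 or more genes. Their first components were compared by a permutation test with 100000 resamples within sex and set, and adjusted over modules. Chromosomes and 10 Mb windows with 10 or more tested genes were tested with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the plots.

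The genes named were set by a rule fixed before the data were examined: the 10 higher and 10 lower genes with the largest absolute log2 fold change among those past the threshold, with an average of at least 1 CPM, an established symbol and the same sign in both sexes and in sheet sets 1 and 2. To these were added up to 3 members past the threshold from each list, and all tested alcohol candidates. For sex, the rule took 4 Y-linked genes, Xist and autosomal genes by the same criteria, and for modules the 5 genes closest to the component of modules that passed or of the 2 modules with the largest wiring change. Some genes that the rule takes are not reported here, and no other gene took their place. Among the 59 genes named for the line difference, 4 overlap an exon of another gene on the same strand (Zfp984, Pcdhga11, Sfi1 and Hspa8, the last with small nucleolar RNA genes) and 17 overlap an exon on the opposite strand, for example Padi2 and Cox5a. Their reads cannot be separated without strand.

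The tests were run on simulated data with known changes. For the line difference, simulated folds of 1.25, 1.5, 2 and 4 were recovered for 86%, 98%, 100% and 100% of 50 genes each among 17071, with 11 false calls in 203. For sex the shares were 86%, 98%, 100% and 100%, with 13 false calls in 205. For the interaction they were 40%, 72%, 98% and 100%, with 9 false calls in 164. A list shifted by 0.1 on the log2 scale gave camera p = 6.22e-48 and an unshifted list p = 0.871. In these simulated counts each gene varied independently and there was no sheet set effect. The changed genes and the list members were drawn from genes averaging over 1 CPM, so the shares recovered do not cover lower genes. Real genes vary together, so these false calls and list p-values do not give the error rates in the real data. Rewired pairs planted in 600 genes gave p = 0.01, the smallest that step can give, against 0.83 without them, and 1 planted window was found. Among 10 simulated modules in 600 genes, 0 passed with none shifted, and the 2 shifted between the lines by 1 SD of the noise passed.

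Alternatives were RLE normalization, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, no set term, leaving out libraries whose median correlation to the others lay over 3 median absolute deviations low, up to 5 surrogate variables from sva 3.50.0, limma-voom with quality weights, single sexes, lines and sets, and thinning to the smallest library. Further alternatives changed the variability test, the tree, the list tests and the windows. Leaving out the library rich in ribosomal RNA, and the windows without the libraries standing apart, were added after seeing the data. Gene ontology terms, which the series design mentions, were not analysed here. No paired analysis was possible because no label links an animal of one line to an animal of the other.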

Results

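RNA was sequenced from hand-dissected ventrolateral striatum of 84 naive adult mice of the SOT and NOT lines, taken at selection generation 4 of breeding for ethanol preference and withdrawal together. The striatum is a forebrain nucleus built mainly of GABAergic medium spiny neurons. The labels place 44 animals in the High Drinker group (21 females, 23 males) and 40 in the Low Drinker group (18 females, 22 males). Total gene counts ran from 22190363 to 41300401 per library, with a median of 31877407 in High Drinker and 30874656.5 in Low Drinker animals. Between 21372 and 22579 genes had at least 1 count in a library. The sex label matched the expression of Y-linked genes and Xist in 84 of 84 libraries. In 1 library, High Drinker 11, a single ribosomal RNA gene, Gm42418, took 10.2% of the counts, against a median of 0.49% for the most abundant gene of a library.

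The first question of the series was which genes differed in expression between the lines. Hspa8, the constitutive heat shock cognate chaperone (ENSMUSG00000015656, chromosome 9, 40800984 to 40805200, mm10), rose from 837 ± 149 CPM in Low Drinker animals (SD, n = 40) to 1106 ± 155 CPM in High Drinker animals (SD, n = 44), a log2 fold change of 0.41 ± 0.05 (SE, adjusted p = 1.65e-08, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). It lay above the Low Drinker median in 41 of 44 High Drinker libraries. Crocc, which encodes the ciliary rootlet protein rootletin (ENSMUSG00000040860, chromosome 4, 141016637 to 141060550), was at 135 ± 72.0 CPM against 62.1 ± 24.8 CPM, a log2 fold change of 1.12 (adjusted p = 4.11e-07, above the Low Drinker median in 38 of 44). Sfi1, which encodes a centrin-binding protein (ENSMUSG00000023764, chromosome 11, 3131850 to 3193463), fell from 145 ± 95.2 CPM to 57.9 ± 33.7 CPM, a log2 fold change of -1.44 (adjusted p = 1.89e-07, below the Low Drinker median in 42 of 44). Nbl1, a secreted antagonist of bone morphogenetic proteins, fell from 70.2 ± 28.8 CPM to 42.6 ± 18.4 CPM (log2 fold change -0.62, adjusted p = 0.00147, below the Low Drinker median in 40 of 44).

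The largest rises by the naming rule were in Zfp984 (log2 fold change 1.63), Crocc, Dcdc2b (1.03), Megf6 (0.92), Rsg1 (0.79), Pcdhga11 (0.78), Sfn (0.77), Tceanc2 (0.76), Padi2 (0.75) and Fut10 (0.75), and 8 of these 10 genes lie on chromosome 4. Padi2, an enzyme that converts arginine residues to citrulline, was at 24.998 ± 9.63 CPM against 15.3 ± 6.32 CPM and lay above the Low Drinker median in 40 of 44 High Drinker libraries. The largest falls were in Eno1b (-2.70), Sfi1, Zfp992 (-1.25), Fmo2 (-0.87), Mns1 (-0.70), Gzmk (-0.69), Mxra8 (-0.65), Ttc12 (-0.63), Nbl1 and Scx (-0.62). Eno1b, a retrotransposed copy of the glycolytic enolase gene Eno1 (chromosome 18, 48045335 to 48048378), was at 9.85 ± 17.2 CPM in High Drinker and 40.2 ± 17.4 CPM in Low Drinker animals (adjusted p = 0.00344, below the Low Drinker median in 39 of 44). Its log2 fold change was unstable, at -1.57 in sheet set 1, -8.83 in sheet set 2, and -4.10 in a linear fit of log2 CPM with a prior of 0.5 added. Eno1 itself (chromosome 4, 150236721 to 150248879), named here after its values were seen, rose from 352 ± 81.8 CPM to 468 ± 89.6 CPM. Reads of Eno1 and Eno1b, of Zfp984 and Zfp992, of Sfi1 and of the protocadherins can align to near-identical copies, and Pcdhga11 shares exons with 25 other genes on its strand, so their values are uncertain.

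**Figure D1:**
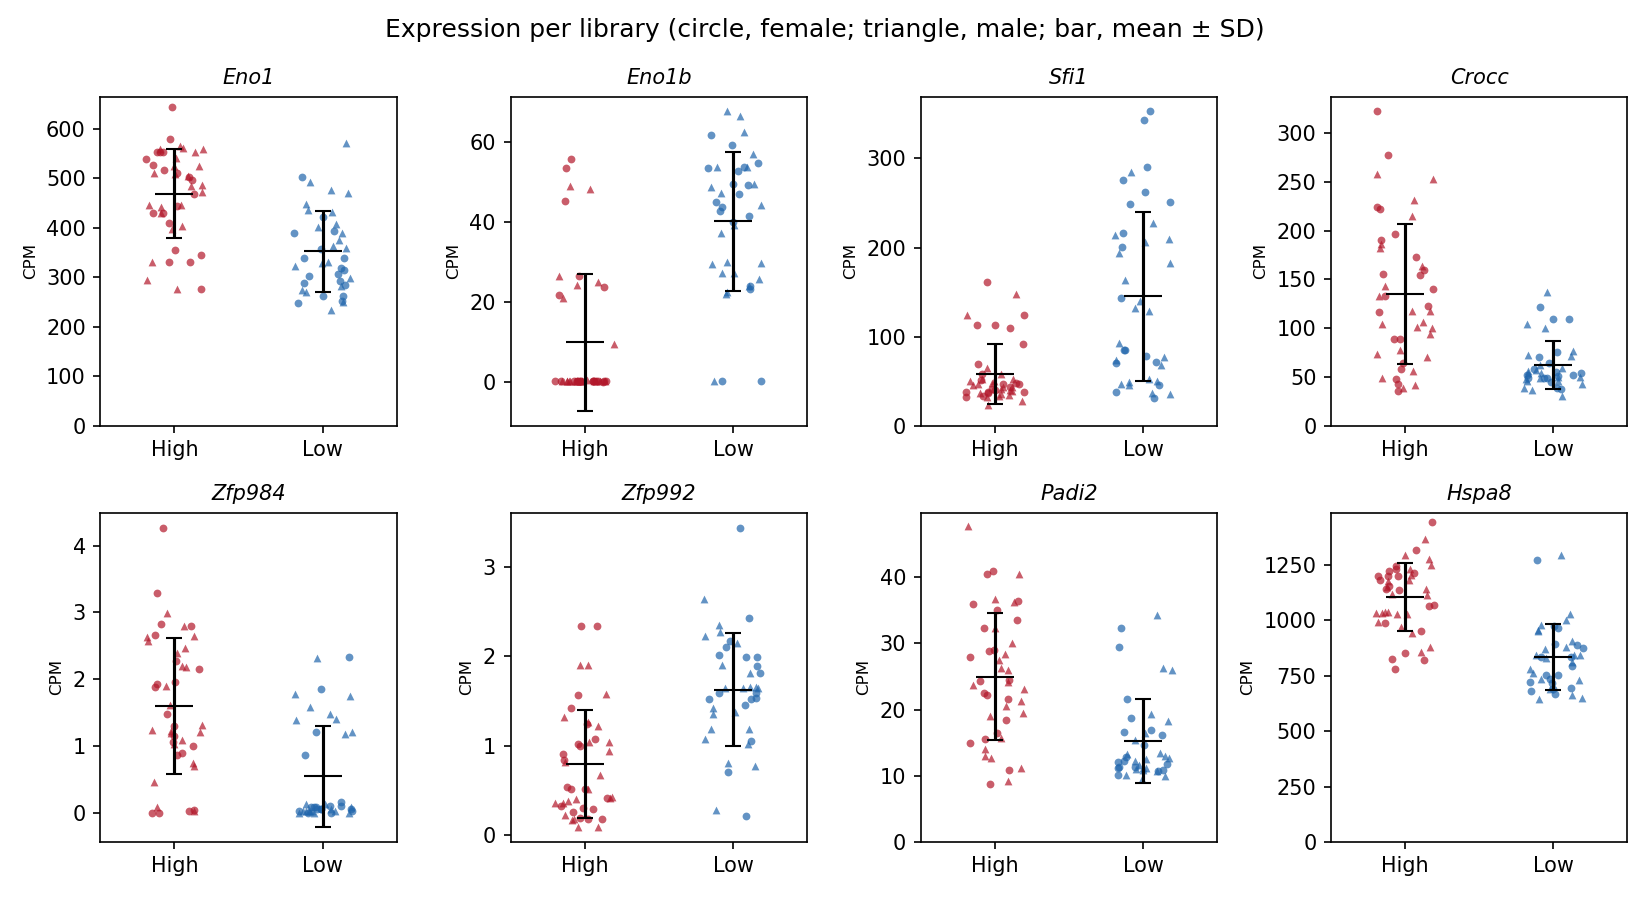
Expression of 8 genes per library, in CPM after TMM scaling (y axis), in High Drinker (n = 44, red) and Low Drinker (n = 40, blue) animals. Circles are females, triangles are males, and the bar and whiskers give the mean and SD. Eno1b lies below 1 CPM in 31 High Drinker and 3 Low Drinker libraries, and Hspa8 means are 1106 and 837 CPM.

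In all, 672 of 17071 tested genes passed an adjusted p of 0.05, of which 317 were higher and 355 lower in High Drinker animals, and 572 were protein coding. At an unadjusted p under 0.05 there were 3078 genes. Most changes were small, with a median absolute log2 fold change of 0.21 among the 672 genes, and 49 genes had an absolute log2 fold change over 1. The lines were unequally spread over the sample sheets, so the fit was repeated within them: sheet set 1 (30 High Drinker, 18 Low Drinker) and sheet set 2 (11 and 19) gave 79 genes each. Among genes tested in both sets 28 were shared, all with the same direction, against 0.183 expected by chance from lists of those sizes. That expectation takes genes as independent, which neighbouring genes are not. On chromosomes 1, 4 and 9 lay 69.6% of the calls in sheet set 1 and 78.5% in sheet set 2. Sheet set 3, with 3 libraries of each line, was not fitted alone. Without 5 libraries whose expression stood apart from the rest (High Drinker 17 and Low Drinker 8, 32, 33 and 34) 425 genes passed, and with 5 surrogate variables added to the model 2468 passed. The labels do not state families or replicate lines, so p-values treat the animals as independent, and a difference between these lines cannot be assigned to selection rather than to drift.

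The genes that differed between the lines were unevenly spread over the genome, with 288 of the 672 (42.9%) on chromosomes 1, 4 and 9, which hold 18.9% of the tested genes. That share was 28% with surrogate variables and 78.5% in sheet set 2 alone, the lowest and highest of the alternatives run. On chromosome 4 the test called 120 of 1067 tested genes (11.2%, against 3.45% elsewhere, adjusted p = 4.51e-25, Fisher's exact test with Benjamini-Hochberg adjustment over chromosomes), 68 of them higher and 52 lower in High Drinker animals. On chromosome 9 it called 83 of 994 genes (8.35%, adjusted p = 6.65e-10), and on chromosome 1 it called 85 of 1163 genes (7.31%, adjusted p = 1.99e-07). The window from 140000001 to 150000000 on chromosome 4 held 35 called genes among 106 (33.02%), and the next window, up to 160000000, held 26 among 110 (23.6%). On chromosome 9 the window from 40000001 to 50000000, which contains Hspa8, held 20 called genes among 95. On chromosome 1 the window from 170000001 to 180000000, which contains Kcnj10, held 20 among 103.

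Of 263 windows of 10 Mb, 11 passed an adjusted p of 0.05. They held 206 of the 672 called genes (30.7%) and 6.45% of the tested genes. The median absolute log2 fold change of called genes was 0.31 inside these windows and 0.18 outside. Apart from the blocks on chromosomes 1 (150000001 to 180000000), 4 (130000001 to 160000000) and 9 (40000001 to 60000000), 3 windows passed, on chromosome 18 (30000001 to 40000000, with the protocadherin clusters, 17 of 160 genes), chromosome 9 (80000001 to 90000000, 9 of 56) and chromosome 8 (30000001 to 40000000, with Fut10, 7 of 35). These 3 depended on the setting: the windows on chromosomes 18 and 9 were lost without the 5 libraries that stood apart, those on chromosomes 9 and 8 with surrogate variables, and all 3 with genes at an adjusted p under 0.01. Neighbouring genes are not independent, so these p-values describe the clustering and do not count separate events.

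**Figure D2:**
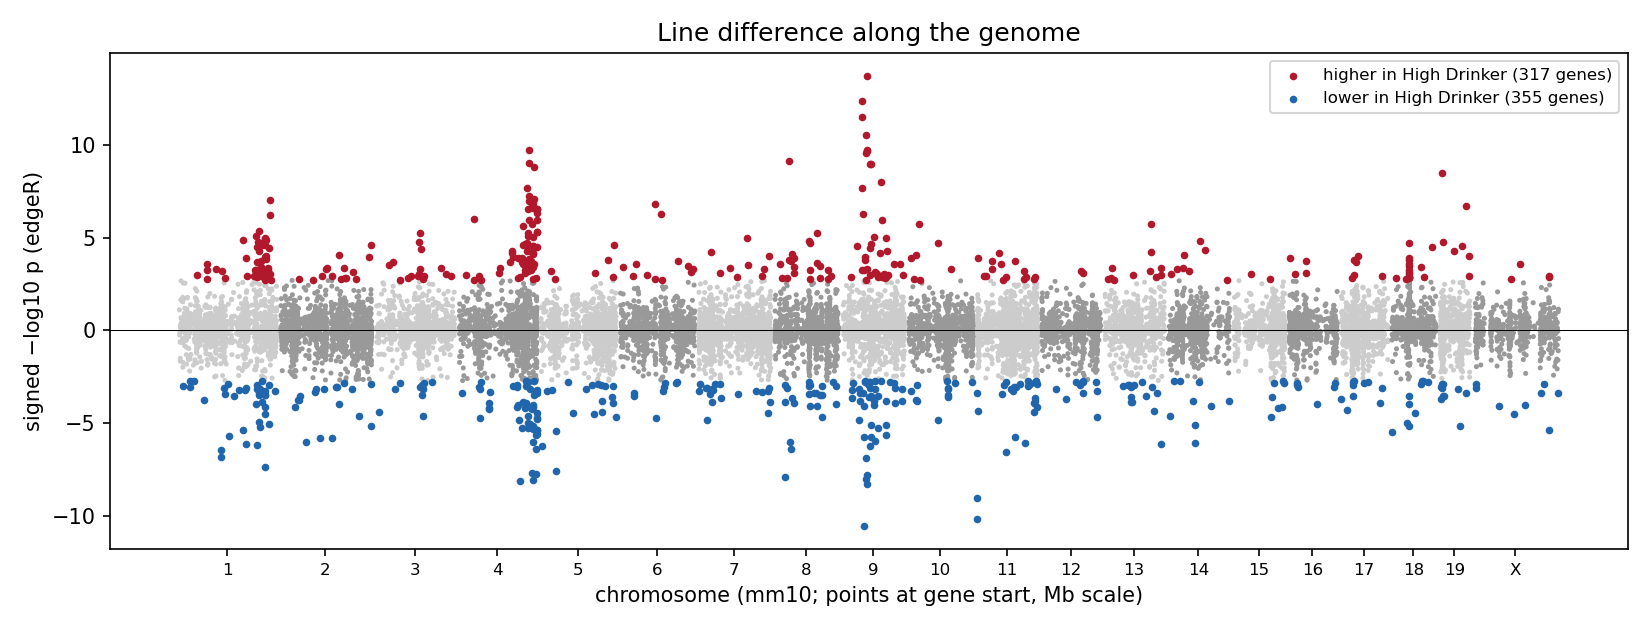
Line difference along the genome for the tested genes on the autosomes and the X chromosome. The x axis gives the gene start on mm10 by chromosome, and the y axis gives the negative log10 of the unadjusted edgeR p, signed by the direction in High Drinker animals. Red points are the 317 genes higher and blue points the 355 genes lower at an adjusted p under 0.05, of which 288 of 672 lie on chromosomes 1, 4 and 9.

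Among genes fixed beforehand for reported links to alcohol preference or withdrawal, 18 of 19 were tested, 2 rose and 1 fell over all genes, and the counts were the same adjusted over the list alone. Mpdz, a scaffold protein with multiple PDZ domains, was at 64.2 ± 14.3 CPM in High Drinker (SD, n = 44) and 55.2 ± 13.03 CPM in Low Drinker animals (SD, n = 40), with a log2 fold change of 0.26 (edgeR adjusted p = 0.0289, above the Low Drinker median in 27 of 44). Kcnj10, the inward rectifier potassium channel of astrocytes, fell from 235 ± 51.0 CPM to 197 ± 39.6 CPM (log2 fold change -0.24, adjusted p = 0.0240, below the Low Drinker median in 38 of 44). The call of Mpdz was lost without the sheet set term (log2 fold change 0.219, adjusted p = 0.0633). That of Kcnj10 was lost without sheet set 3 (-0.214, adjusted p = 0.0561). Both were lost in single sexes and sets, with Mpdz from 0.136 in sheet set 2 to 0.366 in sheet set 1. Kcnj10 ran there from -0.142 in sheet set 2 to -0.276 in sheet set 1. Of the 18 genes 15 did not pass, and 11 of these are reported here. Their log2 fold changes were -0.13 for Npy, 0.11 for Prkce, 0.41 for Scn4b, -0.17 for Glo1, 0.09 for Grm7, 0.16 for Gabra2, 0.03 for Fyn, -0.13 for Kcnj9, 0.16 for Bdnf, 0.13 for Ppp1r1b and 0.002 for Nfkb1. Scn4b and Ppp1r1b varied widely within the lines, with 866 ± 527 CPM and 988 ± 588 CPM in High Drinker animals. With surrogate variables Scn4b passed (0.305, adjusted p = 0.00426), as did Prkce (adjusted p = 0.0188), which also passed by limma-voom (adjusted p = 0.0208). The list as a whole did not pass camera (adjusted p = 0.405, 11 of 18 genes with a positive sign).

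Most members of the lists for cell contact, glutamate receptors and ion channels that passed had a positive sign in High Drinker animals. Among 55 cadherins and protocadherins, which mediate contact between cells, 50 had a positive sign and the median log2 fold change was 0.10. Over all genes 3 rose, namely Pcdhb18 (0.26), Pcdhb13 (0.24) and Pcdhb7 (0.20), and 7 rose adjusted over the list alone (camera adjusted p = 1.67e-09, but adjusted p = 0.511 with an estimated correlation). These 3 genes lie between 37341702 and 37494505 on chromosome 18, in a window that passed, so they are neighbours and not independent. Among 49 synaptic adhesion genes 43 had a positive sign and 1 rose, Slitrk3 (log2 fold change 0.15), while 0 rose adjusted over the list alone (camera adjusted p = 0.000142, adjusted p = 0.672 with an estimated correlation). Among 25 glutamate receptor genes 2 rose, the NMDA receptor subunits Grin2b (591 ± 125 CPM against 496 ± 130 CPM, log2 fold change 0.29) and Grin2c (0.16), and 3 rose adjusted over the list alone (camera adjusted p = 0.00533, adjusted p = 0.511 with an estimated correlation). The call of Grin2c was lost under most alternatives, among them RLE normalization (0.162, edgeR adjusted p = 0.0514). Where it was lost its log2 fold change ran from 0.113 in females alone to 0.22 in males alone. Among 33 sodium and calcium channel genes 29 had a positive sign and 1 rose, Scn2b (0.12), as did 1 adjusted over the list alone (camera adjusted p = 0.00207, adjusted p = 0.511 with an estimated correlation). Scn2b lies in a window of chromosome 9 that passed.

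A further 4 lists passed upward. Among 41 genes of the extracellular matrix and perineuronal net 2 rose, Tnr (0.22) and Cspg4 (0.21), and 3 rose adjusted over the list alone (camera adjusted p = 0.0260, adjusted p = 0.672 with an estimated correlation). Tnr lies in a window of chromosome 1 that passed, and Cspg4 in one of chromosome 9 that passed. Among 11 oligodendrocyte precursor markers only Cspg4 rose, also adjusted over the list alone (camera adjusted p = 0.0260, adjusted p = 0.672 with an estimated correlation). Among 31 genes of interferon response and antigen presentation 2 rose, the GTPases Iigp1 (0.44) and Gbp3 (0.29), and 2 rose adjusted over the list alone (camera adjusted p = 0.0157, adjusted p = 0.806 with an estimated correlation). Among 62 chromatin regulators 1 rose, the histone deacetylase Hdac1 (0.20), and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.0157, adjusted p = 0.672 with an estimated correlation).

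Both lists that passed downward, for energy production and protein synthesis, had few members with a positive sign. Among 74 nuclear genes of oxidative phosphorylation 5 fell over all genes, and adjusted over the list alone 16 fell and 1 rose, with a median log2 fold change of -0.07 and 8 positive signs. Cox5a, a subunit of cytochrome c oxidase, fell from 173 ± 24.4 CPM to 150 ± 14.95 CPM (log2 fold change -0.20, edgeR adjusted p = 0.000408, below the Low Drinker median in 37 of 44), and Ndufa12 had a log2 fold change of -0.18. Cox5a lies in a window of chromosome 9 that passed. Among 77 cytosolic ribosomal protein genes, 4 had a positive sign, the median was -0.10 and 1 fell, Rps14 (-0.16), while 0 fell adjusted over the list alone. Camera gave an adjusted p of 1.11e-10 for oxidative phosphorylation and 1.35e-10 for ribosomal proteins, but adjusted p = 0.672 and adjusted p = 0.779 with an estimated correlation. In all, 10 of 35 lists passed with the preset correlation, 8 upward and 2 downward, and 0 passed with an estimated one. By fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, 4 passed: glutamate receptors, sodium and calcium channels, cadherins and protocadherins, and inflammatory signalling. Genes with short transcripts were lower in High Drinker animals in general: the median log2 fold change ran from -0.06 in the shortest 10% to 0.05 in the longest 10% of genes.

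**Figure D3:**
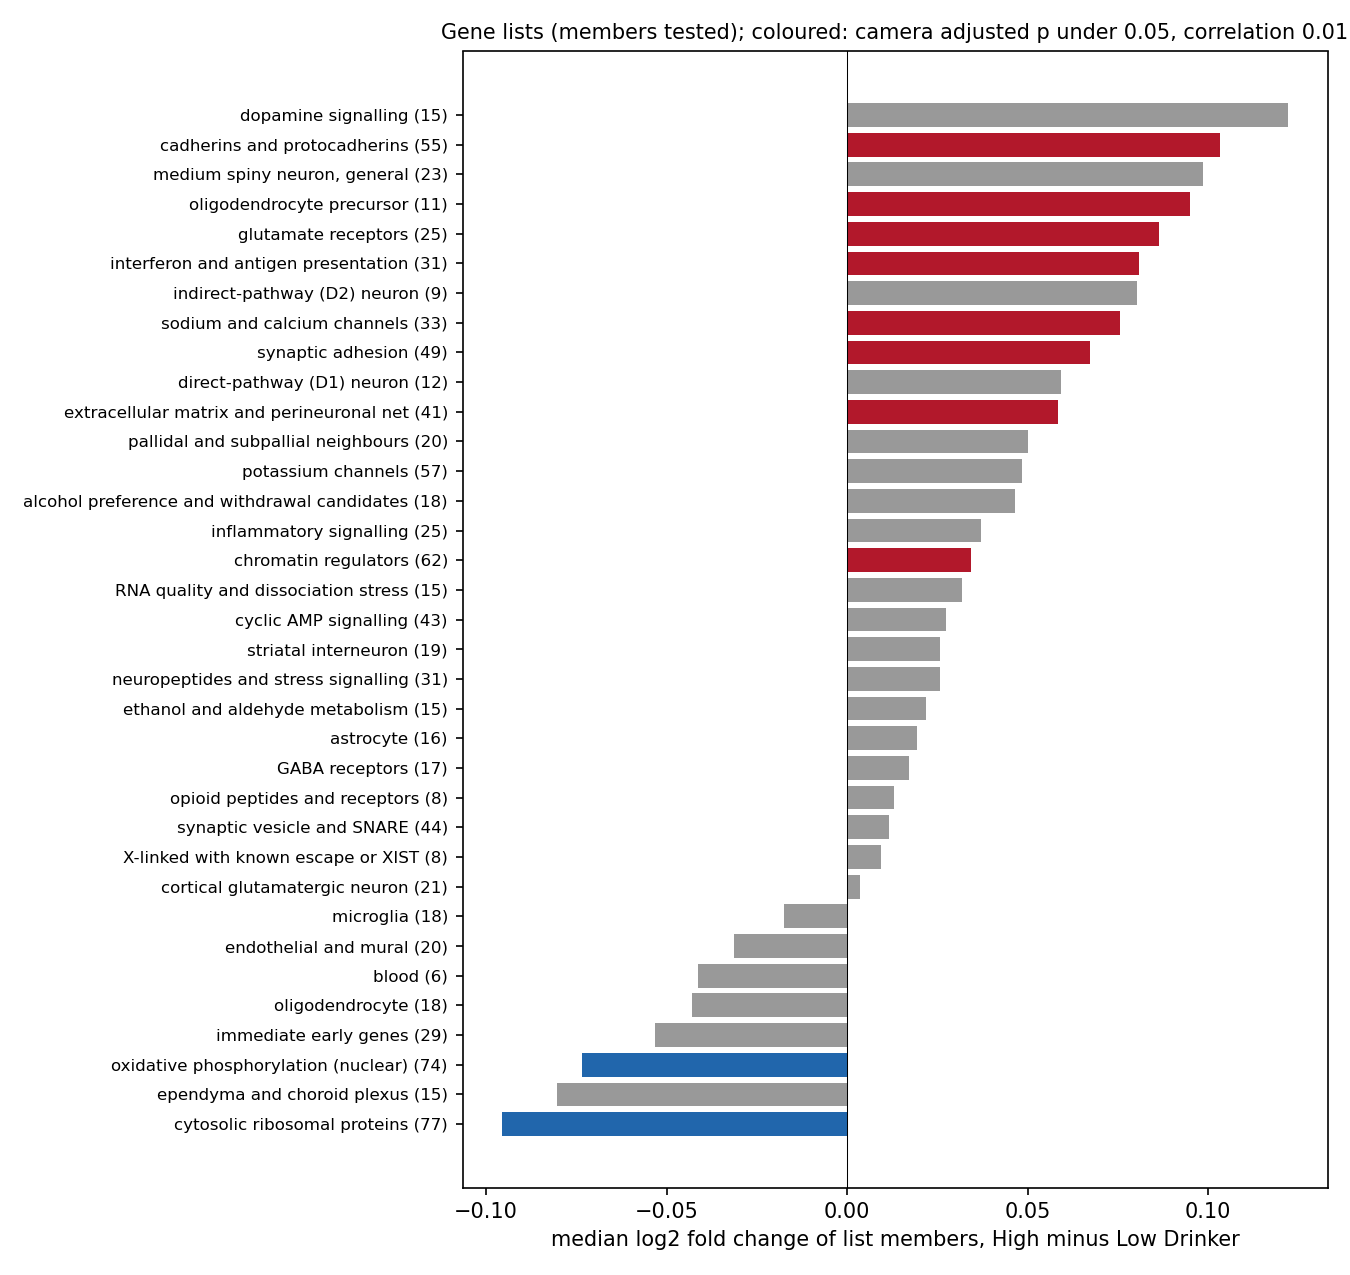
Median log2 fold change (x axis, High minus Low Drinker) of the tested members of 35 gene lists, with the number tested in brackets. Coloured bars are the 8 lists higher (red) and 2 lower (blue) at a camera adjusted p under 0.05 with a preset correlation of 0.01. The lowest bar is the list of 77 cytosolic ribosomal protein genes.

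Apart from the oligodendrocyte precursor markers given above, the cell type marker lists did not pass. The 23 general medium spiny neuron markers had a median log2 fold change of 0.10, with 20 positive signs and 0 genes past the threshold (camera adjusted p = 0.0882), and the direct-pathway and indirect-pathway markers had 0.06 (adjusted p = 0.240) and 0.08 (adjusted p = 0.216). These lists depended on the model: without the sheet set term all 3 passed (adjusted p = 0.000388, 0.0378 and 0.0426), and with surrogate variables the general markers passed (adjusted p = 0.0276). Oligodendrocyte markers passed downward without the 5 libraries that stood apart (adjusted p = 0.0179). The averaged medium spiny neuron score differed by less than its spread between animals, with SDs of 0.66 in High Drinker and 0.83 in Low Drinker animals on the log2 scale (permutation test, two-sided, p = 0.42, adjusted p = 0.883 over 11 marker lists). The main axis of variation, the first component of residual log2 CPM, held 25.2% of the variance between libraries. Its r was 0.925 with Ppp1r1b, 0.912 with Drd1, 0.887 with Adora2a and 0.08 with Mbp. With the cortical markers Slc17a7 and Tbr1 it was -0.817 and -0.851. The lowest medium spiny neuron score (-1.97) and the lowest cortical score (-2.03) of all libraries were among the 5 that stood apart. Camera adjusted p-values were 0.715 for striatal interneurons, 0.197 for astrocytes, 0.216 for oligodendrocytes, 0.715 for microglia, 0.812 for endothelial and mural cells, 0.812 for cortical glutamatergic neurons, 0.931 for pallidal neighbours, 0.135 for ependyma and choroid plexus and 0.785 for blood. Within these lists single genes passed in both directions. The interneuron peptide Cort rose (log2 fold change 0.57), as did the complement genes C1qb (0.32) and C1qc (0.31) and the mural gene Abcc9 (0.20), while the microglial protease Ctss fell (-0.14). Cort, C1qb and C1qc all lie on chromosome 4 between 136880129 and 149126763.

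The remaining lists did not pass either. Camera adjusted p-values were 0.439 for dopamine signalling, 0.785 for opioid peptides and receptors, 0.977 for neuropeptides and stress signalling, 0.564 for GABA receptors, 0.157 for potassium channels, 0.240 for cyclic AMP signalling and 0.240 for ethanol and aldehyde metabolism. They were 0.564 for synaptic vesicle and SNARE genes, 0.0534 for immediate early genes, 0.0534 for inflammatory signalling, 0.785 for X-linked escape genes and 0.564 for RNA quality and dissociation stress. Hspa8 belongs to the list for RNA quality and dissociation stress, and Kcnj10 belongs to the potassium channels. The other single members that passed were Cat (0.10), Syn3 (0.28), Jund (-0.12), Ptgs2 (0.56) and Tnfrsf1b (0.17). Ptgs2 and Tnfrsf1b lie in windows of chromosomes 1 and 4 that passed. Immediate early genes passed downward without the sheet set term (adjusted p = 0.000353), with surrogate variables (adjusted p = 0.0276) and without the 5 libraries that stood apart (adjusted p = 0.0429), and inflammatory signalling passed upward with surrogate variables (adjusted p = 0.0323). These calls used the preset correlation. With an estimated one, run in the main model only, camera gave adjusted p = 0.806 for immediate early genes and 0.511 for inflammatory signalling. The median and the camera direction differed in sign for opioid peptides, neuropeptides and cortical markers, and the mean and the camera direction for GABA receptors and microglia. Without the 5 libraries that stood apart, 15 of the 48 named calls were lost, with adjusted p from 0.0521 to 0.169, while all 15 kept their direction and several their size (0.75 for Pcdhga11, 0.17 for Grin2c, 0.19 for Abcc9 and 0.09 for Cat): Pcdhga11, Grin2c, Scn2b, Cat, Tnr, Slitrk3, Pcdhb18, Pcdhb13, Pcdhb7, Syn3, Jund, Abcc9, Tnfrsf1b, Ndufa12 and Rps14.

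Sex differences, over both lines, passed the edgeR test in 17 genes, 2 of them autosomal. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at 50.2 ± 5.89, 43.2 ± 7.88, 15.3 ± 3.32 and 37.5 ± 5.01 CPM in males (SD, n = 45) and at 0.0325, 0.0285, 0.00578 and 0.0338 CPM in females (n = 39). Xist, which silences the inactive X chromosome, was at 811 ± 188 CPM in females and 0.408 ± 0.58 CPM in males. On the autosomes Sephs2, an enzyme of selenoprotein synthesis, was at 26.5 ± 2.21 CPM in males and 24.5 ± 2.05 CPM in females (log2 fold change 0.13, edgeR adjusted p = 0.00600, above the female median in 36 of 45 males). With fewer animals it did not pass in High Drinker (0.15, adjusted p = 0.213) or Low Drinker animals alone (0.13, adjusted p = 0.967). The other autosomal gene, H2-Q7, named after its values were seen, was at 0.188 ± 0.108 CPM in males and 0.380 ± 0.430 CPM in females. Random splits of the animals gave 2 or more autosomal genes in 6 of 100 cases, the real one included. At an unadjusted p under 0.05 there were 688 genes, and 34 passed without a filter on low counts.

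Whether the line difference itself differed between the sexes was tested with an interaction term. Hspa8 had log2 fold changes of 0.44 in females and 0.37 in males, Crocc 1.18 and 1.06, Sfi1 -1.52 and -1.37, and Padi2 0.75 and 0.75. No gene passed by edgeR (0 of 17071), with 965 genes at an unadjusted p under 0.05, and DESeq2 also called 0. Fitted alone, females gave 35 line differences and males 107, and 19 genes were shared, all in the same direction, against 0.116 expected by chance. That expectation again takes genes as independent. Simulated interactions, in genes averaging over 1 CPM, were recovered for 72% of genes at 1.5-fold and for 98% at 2-fold. Small differences between the sexes were therefore detectable only in part. Without the sheet set term 1 gene passed, the hypothalamic peptide gene Pmch.

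The series also asked whether the lines differed in the variability of expression. The median SD of log2 CPM within line and sex was 0.25 in High Drinker and 0.26 in Low Drinker animals. No gene passed the limma test of absolute deviations (0 of 17071). At an unadjusted p under 0.05 there were 692 genes, a smaller share than the 0.05 of tested genes that chance alone would give. Of these, 233 were more variable in High Drinker and 459 in Low Drinker animals, and this split was not tested. A variance ratio F test called 9 genes, including Omp, more variable in High Drinker animals, and Tnni1, Os9, Amd2 and Pmch, more variable in Low Drinker animals. A smaller prior count of 0.5 called 4 genes, Apoa2, Gm14038, Gm13178 and Gm5909, and removal of surrogate variables called Gm14038. In simulated data SD ratios of 2 were recovered for 28.5% and of 3 for 95.5% of genes.

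Co-expression was compared over the 3000 most abundant tested genes. Between the lines 110275 gene pairs (2.45%) differed in correlation by over 0.5, and 39 of 100 permutations of the line labels gave as many (one-sided permutation p = 0.396). Clustering gave 12 modules. Module 12, with 30 genes led by Trrap, Rai1, Srcap, Zfhx2 and Arid1a, had a first component that was higher in High Drinker animals by 0.586 SD and above the Low Drinker median in 32 of 44 (permutation test, two-sided, adjusted p = 0.0494). It held 2 of the 28 chromatin regulators of the network, which did not pass (adjusted p = 0.747, Fisher's exact test). That call was lost when the tree was cut into 80 clusters (adjusted p = 0.0618) and without the 5 libraries that stood apart (adjusted p = 0.598). The largest differences in mean absolute correlation were in module 2, led by Pum2, Ap1g1, Ddx3x, Crk and B230219D22Rik (0.498 in High Drinker, 0.6005 in Low Drinker, permutation p = 0.228), and in module 5, led by Cdipt, Ap2m1, Atp6v0d1, Atp6v0e2 and Tusc2 (0.458 and 0.556, permutation p = 0.168). Module 3, which holds 58 of 61 ribosomal protein genes and 40 of 45 oxidative phosphorylation genes of the network, contained 30 genes lower and 0 higher in High Drinker animals, and its component differed by -0.364 SD (permutation test, adjusted p = 0.475).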

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

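The counts without the ribosomal RNA library, and the windows without the libraries standing apart, were chosen after seeing the data. All other alternatives were set before the data were examined.

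The line count of 672 genes stayed within 1.5 times under RLE normalization (673 genes, 650 of them shared), no filter (582), a mean of at least 1 CPM (576), DESeq2 (829), no set term (866), limma-voom (1002), without sheet set 3 (590), thinned counts (590) and without the ribosomal RNA library, High Drinker 11 (681). It was 2468 with surrogate variables and 425 without the 5 libraries that stood apart (High Drinker 17 and Low Drinker 8, 32, 33 and 34), and the cause was not tested. Fewer libraries gave 35 genes in females, 107 in males, and 79 in each of sheet sets 1 and 2. Of the 59 genes named, the 48 called ones kept their direction under the alternatives in which they were tested (Iigp1 was not tested at a mean of at least 1 CPM), but calls were lost: 15 without the libraries standing apart, 13 with no filter, 8 without sheet set 3, 7 with no set term, 4 with thinned counts, 3 with limma-voom, 1 each with RLE and with the 1 CPM mean, and 33 to 42 in single sexes and sets, where fewer animals were used.

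The sex count of 17 was 34 with no filter and 37 with surrogate variables (the cause was not tested), and with fewer animals 10 in High Drinker and 11 in Low Drinker animals alone. The interaction count of 0 became 1 without the set term. The variability count of 0 became 9 with the F test, 4 with a prior count of 0.5 and 1 with surrogate variables removed. The module count of 1 became 0 with 80 clusters (adjusted p = 0.0618) and 0 without the libraries standing apart (adjusted p = 0.598). The cause was not tested for these. The count of 10 gene lists was 0 with an estimated correlation and 4 with fry, of which 3 were among the 10 and inflammatory signalling was not. It was 11 with no set term, where extracellular matrix (adjusted p = 0.0818), oligodendrocyte precursors (0.0585) and chromatin regulators (0.0818) were lost. It was 13 with surrogate variables, and 11 without the libraries standing apart, where oligodendrocyte precursors were lost (0.0573). Of 11 windows 7 passed (without those on chromosomes 8 and 18, 1 on chromosome 1 and 1 on chromosome 9) with genes at an adjusted p under 0.01, where fewer genes are counted. With windows of 5 Mb 12 passed. With surrogate variables 10 passed: those on chromosome 8 and from 80 Mb on chromosome 9 were lost, and 1 from 110 Mb on chromosome 13 was new. Without the libraries standing apart 10 passed: those on chromosome 18 and from 80 Mb on chromosome 9 were lost, and 1 from 30 Mb on chromosome 9 was new. Wiring did not pass under any alternative run.

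Among reported alcohol candidates that did not pass, log2 fold changes turned sign as follows, and the cause was not tested. In females alone they were -0.05 for Gabra2, 0.0249 for Kcnj9, -0.0411 for Ppp1r1b and -0.0417 for Nfkb1. In males alone Bdnf was at -0.0118, and in sheet set 1 Ppp1r1b was at -0.164. In sheet set 2 they were -0.0689 for Gabra2, -0.00588 for Fyn, -0.0902 for Bdnf and -0.00223 for Nfkb1. With limma-voom they were -0.00887 for Ppp1r1b and -0.0217 for Nfkb1. Nfkb1 was at -0.00041 with RLE, -0.00222 with no filter and -0.00124 with DESeq2.

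Among lists that did not pass, the camera direction turned as follows, and the cause was not tested. Median log2 fold changes of the voom fit are in brackets and can differ in sign from that direction. With no set term it turned upward for opioid peptides (0.15), neuropeptides (0.0238), microglia (-0.0106), endothelial cells (0.00563) and ependyma (0.0251). It turned downward there for synaptic vesicle genes (-0.0313). With surrogate variables it turned upward for endothelial cells (-0.00207). Without the libraries standing apart it turned upward for cortical neurons (-0.0139) and endothelial cells (-0.00886). It turned downward there for pallidal neighbours (-0.0155) and X-linked genes (-0.0225).

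Thinning every library to the smallest total left 590 line differences among 16444 tested genes, and 540 of them were among the 672. Thinning cannot show what deeper sequencing would add.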

Other observations

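The tests of allele-dependent alignment and of the summed enolase counts, and the random splits for the line, interaction, variability, window and autosomal sex counts, were chosen after the result was seen, as were the 1 and 35 CPM bounds for Eno1b.

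Eno1b fell into separate levels across animals. It lay at or below 0.301 CPM in 31 High Drinker and 3 Low Drinker libraries, between 1 and 35 CPM in 8 and 11, and above 35 CPM in 5 and 26, with no library between 0.301 and 9.38 CPM. Around Eno1 on chromosome 4, Slc2a5, a fructose transporter, rose (log2 fold change 0.68), Masp2, a protease of the lectin pathway of complement, rose (1.12), Cenps, a centromere protein, fell (-0.42) and Clcn6, a chloride transporter of endosomes, fell (-0.18). These genes are outside the naming rule. They were picked, after their values were seen, from the 20 genes that follow Eno1b most closely.

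Gene length went with direction. In the shortest 10% of genes 20 were called higher and 75 lower in High Drinker animals, and in the longest 10% 48 were higher and 7 lower. Across genes, which are not independent replicates, Spearman's rho between length and log2 fold change was 0.278, and 0.214 without the 5 libraries that stood apart. A slope on standardised log2 length was taken per library, after each gene's mean log2 CPM over all libraries was subtracted. These slopes, relative to the average library, were 0.0118 ± 0.04 in High Drinker and -0.013 ± 0.0534 in Low Drinker libraries (SD, n = 44 and 40). Within sex and sheet set the lines differed by 0.0252 (permutation test, two-sided, p = 0.0111).

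Random splits of the animals within sex and sheet set, or within line and sheet set for the sex comparison, were compared with the real grouping. Of 100 splits, the real one included, 2 gave as many line differences (real 672, highest other 934, next 7), which is under 5%. These splits treat the animals as exchangeable within sex and sheet set. Families and replicate lines are not labelled, so chance differences between families are not excluded. The split with 934 calls may reflect a structure of the samples, which was not tested. It put 19.4% of its calls on chromosomes 1, 4 and 9, against 18.9% of tested genes. For windows 1 of 100 gave as many (real 11, highest other 0), but only 1 of the 99 other splits called enough genes to reach 11 windows, so these splits do not decide the window count. For sex 4 of 100 gave as many genes (real 17, highest other 367). The real count is mostly of genes on the sex chromosomes, which correct sex labels must call, so these splits do not test it. The split with 367 calls may again reflect a structure of the samples, which was not tested. For autosomal genes 6 of 100 gave as many (real 2, highest other 357), so chance is not excluded for Sephs2 and H2-Q7. For gene lists 51 of 100 gave as many (real 10, highest other 22), so chance is not excluded as the source of the list count. For the interaction and for variability the real count of 0 was reached by 100 of 100 splits each, as any split must, with highest others of 157 and 13. The split with 157 calls may also reflect a structure of the samples, which was not tested.

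The first pattern is the excess of genes differing between the lines on chromosomes 1, 4 and 9, which held 288 of 672 (42.9%). Poorer alignment of alleles unlike the reference would push a block's genes 1 way if 1 line carried them throughout and their reads were lost. The smaller direction held 37.3% of calls in the most one-sided block, which argues against that form as the whole cause. Reads that move between similar genes, or unlike alleles in both lines, would give both directions and stay open, as do single genes. The main axis of variation (25.2% of the variance) followed striatal against cortical markers, with r = 0.925 for Ppp1r1b and -0.851 for Tbr1. Of as many genes that follow this axis, 4.46% lay in the 11 windows, against 6.45% of tested genes. That argues against a difference in the piece dissected, along this axis, as the source of the excess. Linked alleles that still segregate within the lines may contribute: after line, sex and set were removed, the median absolute correlation of called genes within 10 Mb exceeded that of called genes on different chromosomes by 0.121 (shuffled positions reached 0.0252, p = 0.001, the smallest possible, and uncalled genes reached 0.013). Selection and drift both fix such blocks and stay open, since replicate lines were not analysed here.

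The second pattern is the downward sign of ribosomal and oxidative phosphorylation genes and the upward sign of cadherins and synaptic adhesion genes. A trend with gene length could explain part or all of it, since the central value of 10000 lists matched on length and expression had the sign of the list for all 4 (-0.05, -0.05, 0.02 and 0.03). Against them the ribosomal median stood at percentile 0, oxidative phosphorylation at 1.95, and cadherins and synaptic adhesion at 100 each, but this decides nothing, because the matched lists lack the shared variation of the real ones: the mean r between genes was 0.781, 0.624, 0.287 and 0.215 in the 4 lists and 0.222, 0.209, 0.0395 and 0.1005 in the median matched list. Gene length and a difference in these lists therefore cannot be told apart, and RNA quality and dissection stay open. The called protocadherins lie together in a window of chromosome 18 that passed, and the share of that window in the list result was not tested. By fry, which allows for correlation between genes, cadherins passed (adjusted p = 0.0426) and the other 3 lists did not (0.268, 0.188 and 0.152).

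The third pattern is that Eno1 was higher and Eno1b lower in High Drinker animals. If each read was counted once, reads exchanged between the copies would leave their sum level. The sum differed by 0.33 on the log2 scale (SE 0.05), against 0.46 for Eno1 alone. That argues only against exchange of reads counted once as the whole cause of the Eno1 difference. Reads aligned to both copies may have been dropped, as the multi-mapping setting is not given, so read sharing stays open for Eno1. For Eno1b, reads of 1 Eno1 allele counted at the copy are a candidate explanation: of the 20 genes that follow Eno1b most closely within the lines, 15 start within 10 Mb of Eno1, where 0.252 would fall by chance, and 0 lie near Eno1b. A copy inserted near Eno1 in some animals, or an allele there that acts on Eno1b, would give the same result and stays open.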
